A study of Mus musculus with 6 samples.

How the data were processed

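Single-cell RNA-seq libraries of lung cells from BALB/c mice infected with methicillin-resistant Staphylococcus aureus (MRSA) were compared between 3 samples of mice given PBS by vein and 3 samples of mice given APC by vein. The labels use the abbreviation APC for the treatment without spelling it out, and it is used here in the same way. The samples are labelled as biological replicates 1 to 3 of each group. Per the labels' protocols, lung tissue was minced on ice and digested with trypsin and DNase at 37 °C, red blood cells were lysed, and libraries were made with the 10x Genomics 3' chemistry. The series' design text mentions fluorescence-activated cell sorting, for which the protocols describe no gate, so the shares of cells below may also reflect a sorting step.

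The deposited files hold raw UMI counts per gene and cell barcode, 1 matrix per sample, made with Cell Ranger 7.0.0 per the file headers. The genome build was GRCm38 per the submitters' processing notes. The annotation release was not given in the sources used here, so genes are named by the symbols in the files and no coordinates are given. The 6 matrices hold 58022 barcodes and 33954 genes, of which 38 symbols occur more than once. The lowest UMI count of a barcode was 500. The total UMI count per sample lay between 102098619 and 126235124. No 2 samples were the same library: the chi-square statistic per gene was 73.0 or more for each pair, and at most 46 barcodes were shared.

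Cells with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which removed 1852 barcodes. Scrublet, as implemented in scanpy 1.11.5 and run per sample with an expected rate of 0.08, called 986 doublets (0.648% to 2.29% of a sample's cells), which were removed. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1 with seed 1. Clusters were named from marker lists fixed before the data were examined, and each name stands for a cluster like that cell type ("neutrophil-like" and so on). The fixed list for gamma-delta T cells or innate lymphoid cells was divided after the clusters had been seen, and subtypes of monocytes, dendritic cells and airway epithelial cells were merged. The limits of the naming rule (for example a mean marker z score of 1.6) were also set after the data had been seen. Of the 55184 kept cells, 50003 fell into 29 named classes and 5181 (9.39%) into clusters without a name, because these clusters carried markers of more than 1 class or lineage, matched no class clearly or had a high median doublet score. The unnamed share was 11.6%, 10.4% and 9.52% in PBS and 8.34%, 9.38% and 7.03% in APC (exact two-sided permutation p = 0.1), so every PBS sample lay above every APC sample, and the shares of named classes carry this difference.

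Cells are not replicates, so UMI counts were summed per sample and class, and the sums were tested with the quasi-likelihood test of edgeR 4.0.16 after filterByExpr and TMM, with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. Classes with at least 30 cells in every sample were tested, which left 20 named classes and 2 unnamed clusters. Shares of cells were tested with the same edgeR test on cell numbers, adjusted over the 29 classes, beside an exact two-sided permutation test, which with 3 against 3 samples cannot go below p = 0.1. Gene lists fixed before the data were examined (32 lists) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over all 651 pairs of list and class. The lists cover interferon responses, antigen presentation, cytokines, chemokines, NF-kB targets, neutrophil granule proteins, NADPH oxidase, phagocytic receptors, lysosome, inflammasome, complement, macrophage and lymphocyte activation, metabolism, cell cycle, stress responses, ribosomal and mitochondrial transcripts, mineralisation, apoptosis, immunoglobulin secretion, endothelial activation, surfactant and extracellular matrix. Fold changes are log2 of APC over PBS with the standard error (SE) of the fit, levels are CPM, the summed UMIs of a gene scaled to the same library total, and means are given ± SD with n = 3 per group. Unless another test is named, p-values of genes come from edgeR and those of lists from camera. Those of edgeR rest on the spread between the labelled biological replicates, while camera at a preset correlation ranks the genes of a list against the other genes.

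Genes were named by a rule fixed before the data were examined. In the 5 named classes with most cells up to 10 genes per direction were named, and in each other class up to 4, if they had an adjusted p under 0.05, a mean log2 CPM of at least 5 and no overlap between the groups. Where fewer than 3 genes qualified, the 5 genes with the smallest p at that level are given as values only. Members of called lists are named as examples, at most 4 per list by smallest p. Genes outside this rule are said to be so.

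The edgeR step was tested on simulated counts drawn from the real means and library sizes. Only genes with a mean log2 CPM of at least 5 were changed, so the recovery below holds for such genes. The spread between samples followed the fitted trend, without the extra spread of single genes, and many genes were changed at once. Recovery in the real counts can therefore be lower. In real general capillary cells Ccn2 (-1.32), Hlx (-1.25) and Fgfr3 (1.15) had an edgeR adjusted p of 0.0935 and did not pass. For general capillary endothelial cells (12641 genes) it recovered 59.7% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 10 unchanged genes called. For monocytes (9681 genes) it recovered 11.9%, 80.6% and 100% at these fold changes, with 7 unchanged genes called. The list test of these simulated general capillary counts (camera) gave 7.98e-27 for a raised list and 0.479 for an unchanged one as its p-values. Genes were drawn independently of each other there, so this does not test the preset correlation on real counts. Alternatives planned before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0, a replicate block, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial UMIs), doublets kept, clustering resolutions 0.5 and 2, an estimated correlation for lists, other denominators and TMM for cell numbers, and leaving out each sample in turn. Added after seeing the data were neutrophils without cluster 50 and libraries of a class thinned to 1 total.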

Results

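Lung cells were profiled by droplet-based single-cell RNA-seq from mice infected with MRSA, a methicillin-resistant form of Staphylococcus aureus, and then given PBS (3 samples, the control) or APC (3 samples). The design asks how lung cells of infected mice differed after the treatment. The files held 9766, 10032 and 9418 barcodes for PBS replicates 1 to 3 and 8615, 10107 and 10084 for APC replicates 1 to 3. Total UMIs were 110879670, 102098619 and 118021539 in PBS and 110429568, 126235124 and 108222512 in APC.

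Depth and number of cells were compared between the groups. The median UMI count per kept cell was 7406 ± 419 in PBS and 8358 ± 702 in APC (SD, n = 3 each, exact two-sided permutation p = 0.2). Medians of 2701 ± 19 and 2824.5 ± 150 genes were detected (exact permutation p = 0.4). The median mitochondrial share was 2.34% ± 0.0597 in PBS and 2.22% ± 0.118 in APC (n = 3, exact permutation p = 0.3). The number of kept cells was 9209 ± 235 and 9186 ± 769 (n = 3, exact permutation p = 1).

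The lungs held immune, endothelial, epithelial and mesenchymal cells, of which fibroblasts (5829 cells), general capillary endothelial cells (5599), neutrophils (5389), B cells (5258) and T cells (4761) were the most numerous named classes. Mesothelial cells, which line the lung surface, made up 0.0901% ± 0.0367 of cells in PBS and 0.372% ± 0.230 in APC. Monocytes, the blood-borne precursors of macrophages, made up 1.94% ± 0.464 and 3.24% ± 0.338. Natural killer cells, which are cytotoxic innate lymphocytes, made up 4.31% ± 1.83 and 2.37% ± 1.40. Alveolar type 1 cells, the thin cells of gas exchange, made up 2.68% ± 0.0495 and 3.53% ± 0.533 (SD, n = 3 for each share).

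Of the 29 named classes, 0 differed in share past the threshold by edgeR, and 2 did at an unadjusted p under 0.05. These were mesothelial cells (log2 fold change 2.03, SE 0.66, edgeR adjusted p = 0.442) and monocytes (0.74, SE 0.32, edgeR adjusted p = 0.703). The exact permutation p was 0.1, the smallest possible, for mesothelial cells, monocytes and alveolar type 1 cells, whose shares did not overlap between the groups, and 0.2 for natural killer cells. No other of the 29 classes separated in this way, and 10% of classes are expected to do so by chance. Mesothelial cells numbered only 12, 8 and 5 in PBS replicates 1 to 3 and 12, 36 and 57 in APC replicates 1 to 3. Fibroblasts were at 9.36% ± 0.683 and 11.6% ± 2.29 (n = 3, exact permutation p = 0.2). Neutrophils were at 8.05% ± 5.14 and 11.5% ± 4.54 (exact permutation p = 0.5), T cells at 9.70% ± 2.30 and 7.65% ± 2.48 (exact permutation p = 0.2) and B cells at 10.5% ± 1.77 and 8.74% ± 3.38 (exact permutation p = 0.6, n = 3 for each). General capillary endothelial cells were at 10.4% ± 1.77 and 9.88% ± 0.449 (n = 3, exact permutation p = 0.7). The neutrophil log2 fold change of 0.52 was 1.18 without PBS replicate 3, 0.27 without PBS replicate 1, 0.28 without PBS replicate 2 and 0.15 without APC replicate 3. The B cell log2 fold change of -0.26 was 0.01 without APC replicate 3, -0.55 without APC replicate 1 and -0.14 without PBS replicate 3. That of general capillary cells of -0.07 was 0.06 without PBS replicate 2, -0.19 without PBS replicate 3 and -0.03 without APC replicate 1. For natural killer cells the value of -0.86 was -0.54 without PBS replicate 2, -0.55 without APC replicate 2 and -1.44 without APC replicate 3, and for fibroblasts that of 0.31 was 0.15 without APC replicate 2. For T cells the value of -0.34 was -0.23 without PBS replicate 1, -0.53 without PBS replicate 3, -0.64 without APC replicate 1 and -0.19 without APC replicate 3.

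**Figure D1:**
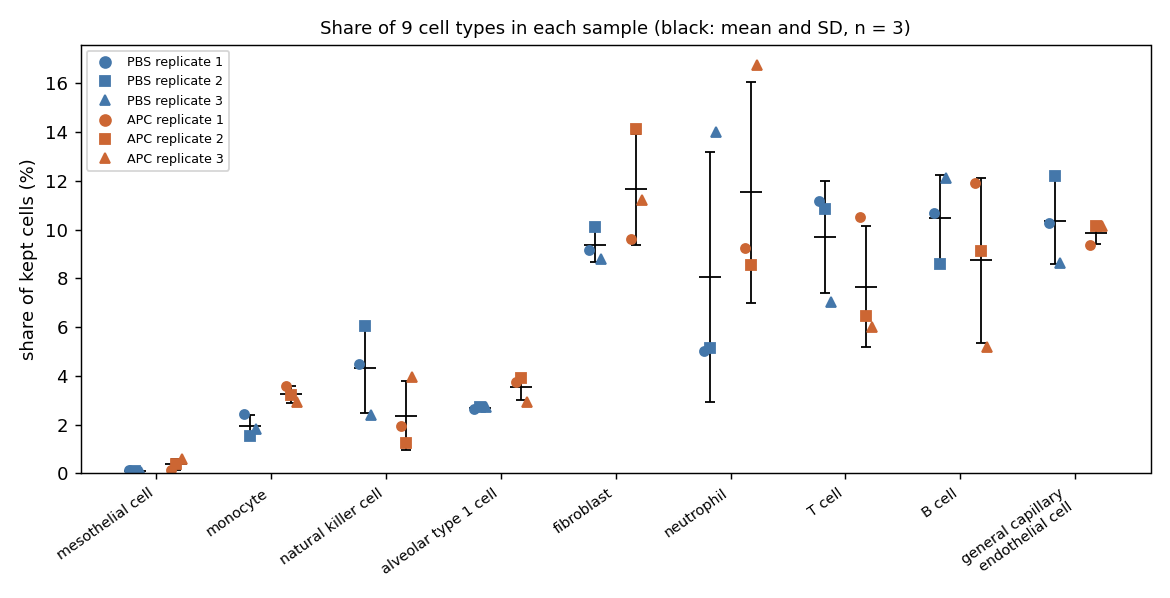
Share of kept cells (%, y axis) for 9 cell types (x axis) in each of 3 PBS and 3 APC samples, with the mean and SD of each group in black. Monocytes lie between 1.55% and 2.45% in PBS and between 2.92% and 3.59% in APC, while the neutrophil shares of both groups overlap.

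Within cell types, genes past the threshold were few and lay in natural killer cells, venous endothelial cells, general capillary endothelial cells and monocytes. In monocytes Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, rose from 17.7 ± 3.46 to 94.5 ± 20.2 CPM (log2 fold change 2.42, SE 0.22, adjusted p = 0.00927, n = 3). In venous endothelial cells Nos3, the endothelial nitric oxide synthase, rose by a log2 fold change of 1.14 (SE 0.14) and Lsamp, a cell adhesion molecule, by 1.75 (SE 0.22). In the same cells Ccn2, a matricellular growth factor gene, fell from 527 ± 129 to 170 ± 17.3 CPM (-1.63, SE 0.19), with adjusted p = 0.0206 for all of these. In general capillary endothelial cells Hspa12b, a heat shock protein 70 family gene of endothelium, rose from 76.7 ± 1.46 to 140 ± 9.49 CPM (0.87, SE 0.09, adjusted p = 0.0494). Other splits of the 6 samples into 3 and 3 called up to 12 genes in venous cells, 1 in monocytes and 0 in general capillary cells. The calls of the labelled groups ended without single samples. The edgeR adjusted p of Areg in monocytes was 0.207 without PBS replicate 1, 0.186 without PBS replicate 3 and 0.0539 without APC replicate 3. In venous cells Nos3 and Lsamp had 0.148 without PBS replicate 1, Ccn2, Nos3 and Lsamp 0.206, 0.264 and 0.271 without PBS replicate 2, and all of these 0.116 without APC replicate 3. Hspa12b in general capillary cells had 0.194, 0.146 and 0.0682 without PBS replicates 1, 2 and 3, and 0.0985 and 0.252 without APC replicates 1 and 3. Its call also ended with RLE size factors, the replicate block, the stricter cell filter and resolution 2, and held in 5 of 14 alternatives.

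Natural killer cells had 9 genes past the threshold. The count was 0 with doublets kept, 1 at resolution 0.5 and 3 with thinned libraries, but 9 with RLE size factors or the stricter filter and 11 at resolution 2. Splits of the 6 samples other than the labelled one gave as many genes in these cells. The split of PBS replicates 1 and 2 and APC replicate 3 from the rest called 22. That of PBS replicates 1 and 3 and APC replicate 1 called 9. Tnfrsf9, the co-stimulatory receptor 4-1BB, rose from 124 ± 5.65 to 215 ± 34.3 CPM (log2 fold change 0.82, SE 0.12, adjusted p = 0.0393). Nrgn, which was also the leading gene of unnamed cluster 40 with the platelet genes Ppbp and Pf4, rose by 1.30 (SE 0.19), the integrin gene Itgav by 0.75 (SE 0.12) and Sdf2l1, a gene of the endoplasmic reticulum chaperone system, by 0.92 (SE 0.15). Lower in APC were Fhit (-0.83, SE 0.14), Hs3st3b1, a heparan sulfate sulfotransferase gene (-0.79, SE 0.14), and Sftpa1 (-0.97, SE 0.16), a surfactant protein gene of alveolar type 2 cells. Crtam (1.79, SE 0.30) and Retnlg (3.01, SE 0.51), a neutrophil transcript, also passed, below the CPM limit of the naming rule. Adjusted p of these genes lay between 0.0393 and 0.0473. By edgeR it was above 0.05 for all 9 in natural killer cells without PBS replicate 1 (0.121 to 0.339), PBS replicate 2 (0.066 to 0.13) or APC replicate 2 (0.115 to 0.184). It was also above 0.05 for Hs3st3b1 (0.0566), Crtam (0.0504) and Retnlg (0.0504) without PBS replicate 3, and for Itgav (0.0916), Sftpa1 (0.117) and Sdf2l1 (0.0916) without APC replicate 1. Without APC replicate 3 this held for Nrgn (0.0849), Tnfrsf9 (0.0789), Fhit (0.139), Sftpa1 (0.135), Sdf2l1 (0.154) and Hs3st3b1 (0.183). As measured beside them, Sftpa1 had a median of 41.8 ± 4.00 CPM in PBS and 26.5 ± 2.98 in APC over the cell types outside alveolar type 2 cells, and Retnlg 2.70 ± 0.861 and 22.9 ± 14.2 outside neutrophils and monocytes (n = 3). For Sftpa1 and Retnlg a change within natural killer cells was thus not separated from RNA of their source cells.

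**Figure D2:**
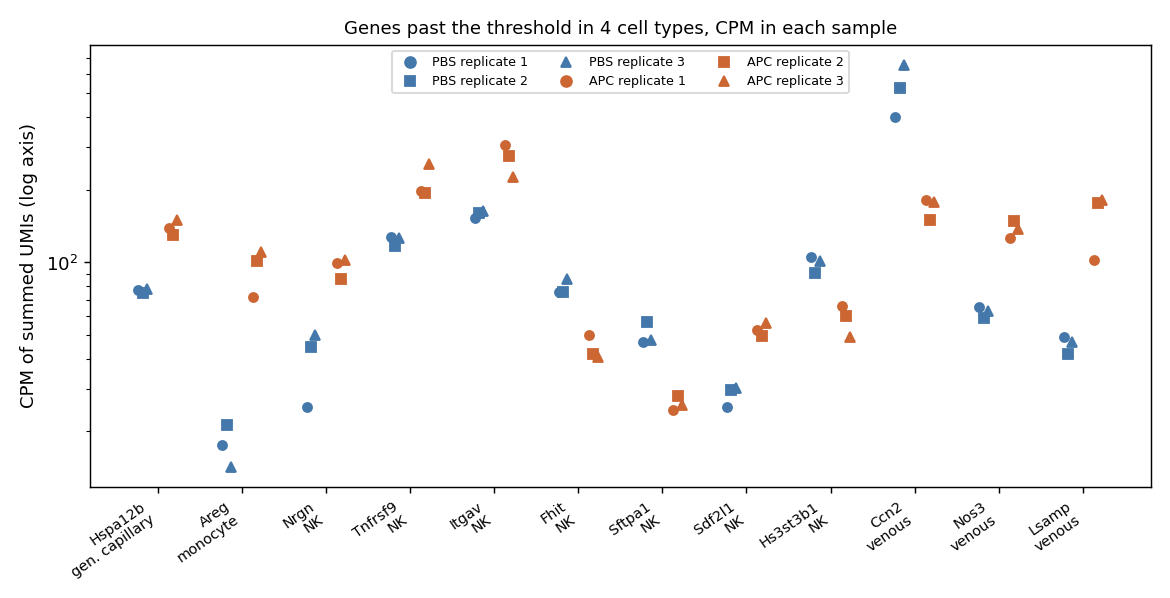
CPM (y axis, log axis) of the 12 genes named by the rule in the cell type in which they passed the threshold (x axis), 1 point per sample. For every gene the 3 APC samples lie outside the range of the 3 PBS samples, for example Areg in monocytes between 14.3 and 21.2 CPM in PBS and between 71.6 and 110 in APC.

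Over all 22 tested cell types and clusters and 229214 tests, edgeR called 14 genes, of which 10 were higher and 4 lower in APC, and 13415 (5.85%) had an unadjusted p under 0.05. DESeq2 called 371. It was run on all genes with a count and with its own filter, so its counts here and below cover another set of genes. In 18 of the 22 edgeR called 0, with 239 to 1132 genes per cell type at an unadjusted p under 0.05, and DESeq2 called 182 over these 18. Leaving out a sample moved the count of 14 to 2 without PBS replicate 1, 5 without PBS replicate 2, 53 without PBS replicate 3, 86 without APC replicate 1 and 29 without APC replicate 2. Natural killer cells had 0 without PBS replicate 1 or APC replicate 2, 1 without PBS replicate 2 and 15 without PBS replicate 3. Venous cells had 0 without PBS replicate 2 or APC replicate 3, 1 without PBS replicate 1, 19 without PBS replicate 3, 8 without APC replicate 1 and 24 without APC replicate 2. Monocytes had 0 without PBS replicate 1, PBS replicate 3 or APC replicate 3, 2 without PBS replicate 2 and 44 without APC replicate 1. General capillary cells had 0 without PBS replicate 1 or APC replicate 3, 3 without APC replicate 1 and 2 without APC replicate 2. None of the 14 genes changed direction without 1 sample, but their groups did not overlap, so leaving out a sample could hardly turn them.

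List calls here and below used the preset correlation. With it, the 9 other splits of the 6 samples into 3 and 3 called 157 to 262 pairs, against 141 for the labelled groups. In neutrophils of APC samples the list of granule protein genes, the antimicrobial cargo made during maturation in the bone marrow, was called higher, and those of NF-kB targets and interferon-gamma response genes lower. All 15 granule genes tested had positive fold changes (median log2 fold change 1.10, camera adjusted p = 9.09e-09), among them Mmp8 (1.76, SE 0.44), Lyz2 (1.18, SE 0.29) and Pglyrp1 (1.32, SE 0.32). The adjusted p was 0.933 with an estimated correlation. The ribosomal, oxidative phosphorylation and mitochondrially encoded lists were also called higher, with medians of 0.39, 0.37 and 0.47 (0.933 to 0.937 with an estimated correlation). All 18 NF-kB genes (median -0.58, adjusted p = 0.00776) and all 17 immediate-early genes (median -0.54, adjusted p = 1.82e-05) had negative fold changes, for example Nfkbia at -0.99 (SE 0.46) and Atf3 at -1.33 (SE 0.42). With an estimated correlation the adjusted p of these lists was 0.944 and 0.933. Without PBS replicate 3 the median of the NF-kB list turned to 0.03. The interferon-gamma list (median -0.46) and the major histocompatibility complex (MHC) class I list (median -0.28) were lower too, with H2-Q6 at -2.54 (SE 0.49). The complement list was higher (median 0.46), with Cfp at 1.10 (SE 0.29). For the interferon-gamma, MHC class I and complement lists it was 0.933 with an estimated correlation. Leaving out 1 sample brought the neutrophil adjusted p above 0.05 for NF-kB (0.0608 without APC replicate 3 and 0.531 without PBS replicate 3) and complement (0.0638 without APC replicate 3, 0.0738 without PBS replicate 1 and 0.198 without PBS replicate 2). The same was so for interferon-gamma (0.113 without APC replicate 2 and 0.102 without PBS replicate 3). Neutrophil medians that moved by over 1.5 times were -0.43 (MHC class I) without APC replicate 1, and 0.20 (ribosomal), -0.23 (interferon-gamma), 0.65 (granule protein) and 0.17 (oxidative phosphorylation) without APC replicate 2. Further neutrophil medians were 0.17 (complement) without PBS replicate 1, and 0.09 (complement) without PBS replicate 2. Neutrophil medians were also 0.97 (complement) and -0.27 (interferon-gamma) without PBS replicate 3.

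The neutrophil class was made of 3 clusters that the samples filled unequally. Cluster 31, led by the granule genes Ngp, Camp and Ltf, held 5.77%, 7.05% and 5.76% of neutrophils in PBS and 15.4%, 76.0% and 25.9% in APC. Cluster 50, led by Il1rn, Ccl3 and Tnf, held 56.6% in PBS replicate 3 and between 0.951% and 14.8% in the other samples. The neutrophil list calls were made over the whole class, and whether they hold within each cluster was not tested. A difference in the mix of clusters is thus not separated from a change within cells. No single gene passed the threshold in neutrophils by edgeR (0 of 9582), while 1132 had an unadjusted p under 0.05 and DESeq2 called 49. Adjusted over the list alone, 7 granule genes were higher and 6 MHC class I genes lower. The genes with the smallest p had values of 1.27 (Snai1, SE 0.20), 2.19 (Retnlg, SE 0.41), 1.76 (Ly6g, SE 0.37), 0.87 (Degs1, SE 0.18) and 1.76 (Ceacam10, SE 0.37), each with an adjusted p of 0.39.

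In fibroblasts, the matrix-producing cells of the lung wall, the list of immediate-early genes, the fast transcriptional response to stimulation or cell handling, was called higher in APC, with 16 of 17 members above 0 (median log2 fold change 0.38, camera adjusted p = 2.69e-14). With an estimated correlation the adjusted p of this list was 0.933, and that of the other fibroblast lists of this paragraph lay between 0.933 and 0.952. Egr1 was at 0.57 (SE 0.12), Nr4a1 at 0.80 (SE 0.21) and Btg2 at 0.53 (SE 0.14), and 7 members were higher when adjusted over the list alone. NF-kB targets (median 0.25, adjusted p = 0.000596) and the heat shock list (median 0.16, adjusted p = 8.37e-05) were called higher as well, with Nfkbiz at 0.40 (SE 0.12), Hspa5 at 0.47 (SE 0.11) and Hspa8 at 0.53 (SE 0.12). Complement (0.17), type I interferon (0.27), immunoglobulin secretion (0.29) and granule protein (0.27) lists had positive medians, and the mitochondrially encoded list a negative one (-0.14). Granule and immunoglobulin genes are transcripts of neutrophils and plasma cells, whose genes S100a8, Retnlg and Igkc were also measured across other cell types. Without APC replicate 2 the medians of the granule protein and immunoglobulin lists turned to -0.02 and -0.23, and without PBS replicate 2 that of the complement list turned to -0.05. In fibroblasts the adjusted p lay above 0.05 without 1 sample for NF-kB (0.123 without APC replicate 2 and 0.171 without PBS replicate 2) and complement (0.499 without PBS replicate 2). Others were heat shock (0.0574 without PBS replicate 3) and immunoglobulin secretion (0.992 without APC replicate 2, 0.216 without PBS replicate 1 and 0.68 without PBS replicate 2). Further such lists were mitochondrially encoded (0.749 without APC replicate 2, 0.33 without PBS replicate 2 and 0.217 without PBS replicate 3) and granule protein (0.0641 without APC replicate 2). So it was for type I interferon (0.32 without APC replicate 1, 0.37 without APC replicate 3 and 0.119 without PBS replicate 1). Fibroblast list medians that moved by over 1.5 times were 0.06 (complement), 0.43 (immunoglobulin secretion), 0.41 (granule protein) and 0.10 (type I interferon) without APC replicate 1, and 0.08 (NF-kB), 0.28 (complement), 0.25 (heat shock), -0.04 (mitochondrially encoded) and 0.57 (type I interferon) without APC replicate 2. Further fibroblast list medians were -0.22 (mitochondrially encoded), 0.58 (granule protein) and 0.10 (type I interferon) without APC replicate 3, and 0.36 (heat shock), -0.21 (mitochondrially encoded) and 0.18 (granule protein) without PBS replicate 1. Fibroblast list medians were also 0.09 (NF-kB), 0.13 (immunoglobulin secretion) and 0.48 (granule protein) without PBS replicate 2, and 0.50 (NF-kB), 0.78 (complement), 0.61 (immunoglobulin secretion), -0.09 (mitochondrially encoded) and 1.21 (granule protein) without PBS replicate 3.

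The surfactant list was lower in fibroblasts (median -0.34, adjusted p = 9.52e-21, adjusted p = 0.268 with an estimated correlation), and 7 of its 18 members were lower when adjusted over the list alone. Fibroblasts were made of 3 clusters, of which cluster 9, led by Dcn, held 36.1%, 21.4% and 41.1% in PBS and 40.1%, 45.8% and 47.1% in APC, and cluster 15, led by C7, 45.7%, 66.1% and 28.1% in PBS and 33.0%, 34.8% and 34.4% in APC. Its largest member, Sftpc, was at 550 ± 138 CPM in PBS and 141 ± 8.94 in APC (-1.96, SE 0.20). Alveolar type 2 cells, the source of surfactant proteins, held 155790 ± 4874 and 147610 ± 8074 CPM of Sftpc (n = 3, exact permutation p = 0.2). By edgeR 0 of 14606 genes passed in fibroblasts, with 558 at an unadjusted p under 0.05 and 21 called by DESeq2. Besides Sftpc and Sftpa1 (-1.77, SE 0.30), the genes with the smallest p were Cirbp (-0.90, SE 0.10, adjusted p = 0.265), Stip1 (0.49, SE 0.08) and Snhg3 (-0.54, SE 0.11). Without PBS replicate 3 the surfactant median of fibroblasts was -0.22.

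In endothelial cells of general capillaries, arteries and veins the endothelial activation list was called higher in APC. This list holds adhesion molecules, vasoactive genes, cytokines and the chemokine gene Cxcl1, and its name does not establish a state of the cells. The medians were 0.46, 0.26 and 0.30, with camera adjusted p = 0.00563, 0.019 and 0.000866, and 0.933 for each with an estimated correlation. In general capillary cells Nos3 was at 0.66 (SE 0.21), Icam2 at 0.35 (SE 0.11) and Cxcl1 at 0.78 (SE 0.21), while Angpt2, an antagonist of vessel stability, was at -1.25 (SE 0.24). In venous cells Angpt2, a member of the list, was at -2.35 (SE 0.43), against the direction of the call. The neutrophil-attracting chemokine gene Cxcl1 was at 1.91 (SE 0.40) there. Cxcl2, which is in the chemokine list and not in the activation list, was at 2.77 (SE 0.45). A few venous cells of APC samples held much RNA of the neutrophil gene S100a8. Its level in APC replicate 1 was 632 CPM, and 30.4 without 2 of the 56 cells. For APC replicate 3 it was 164 CPM, and 89.5 without 1 of the 74 cells. The PBS samples and APC replicate 2 had no such venous cells. Whether these cells raised Cxcl2 and Cxcl1 was not tested. Sele, an adhesion molecule for leukocytes, was at 1.71 (SE 0.57) in arterial cells. Adjusted over the list alone, 5 members of the activation list passed in general capillary cells and 3 in venous cells, where Nos3 alone passed over all genes. The adjusted p of this list was above 0.05 without 1 sample in general capillary cells (0.0542 without APC replicate 2), arterial cells (0.228 without APC replicate 2 and 0.28 without PBS replicate 2) and venous cells (0.0549 without PBS replicate 1). General capillary medians that moved by over 1.5 times were 0.69 (endothelial activation) without APC replicate 1, and 0.29 (endothelial activation) without APC replicate 2. Further general capillary medians were 0.78 (endothelial activation) without PBS replicate 3. Arterial medians that moved by over 1.5 times were 0.12 (endothelial activation) without APC replicate 2, and 0.43 (endothelial activation) without APC replicate 3.

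Called higher in general capillary cells were also the lists of heat shock genes (12 of 13 members above 0, median 0.40, adjusted p = 2.9e-07) and MHC class II genes (8 of 8, median 0.51, adjusted p = 0.00706). The adjusted p of these and the following 3 lists of these cells was 0.933 to 0.944 with an estimated correlation. Hspd1 was at 0.45 (SE 0.09), Dnaja1 at 0.55 (SE 0.12) and the class II regulator Ciita at 0.85 (SE 0.26). The NF-kB (0.13) and immunoglobulin (0.51) lists were higher and the surfactant list lower (-0.35). Without APC replicate 2 the NF-kB and immunoglobulin medians turned to -0.01 and -0.09. Lists of general capillary cells with an adjusted p above 0.05 without 1 sample were MHC class II (0.709 without APC replicate 1) and NF-kB (0.592 without APC replicate 2, 0.0899 without PBS replicate 1 and 0.37 without PBS replicate 2). The same was so for immunoglobulin secretion (0.41 without APC replicate 2, 0.162 without PBS replicate 1 and 0.0805 without PBS replicate 2). The class was made of clusters 19 and 39, and cluster 39, led by Gpihbp1, held 21.9%, 10.9% and 39.1% in PBS and 22.2%, 25.1% and 26.9% in APC. Next to Hspa12b, 1204 genes had an unadjusted p under 0.05 and DESeq2 called 116. Values with an adjusted p of 0.0935 were -1.32 for Ccn2 (SE 0.16), -1.25 for Hlx (SE 0.17), 1.15 for Fgfr3 (SE 0.16) and -0.82 for Fam102b (SE 0.12). In venous cells the interferon-gamma (-0.35), type I interferon (-0.34), MHC class I (-0.29) and oxidative phosphorylation (-0.12) lists were called lower (0.933 to 0.944 with an estimated correlation). The chemokine (1.20), NF-kB (0.19), NADPH oxidase (0.98) and granule protein (1.34) lists were called higher there (0.933 for each). Among the members of the NADPH oxidase and granule protein lists, which are leukocyte genes, were Rac2 (1.78, SE 0.30) and Pglyrp1 (1.61, SE 0.40). Neutrophil RNA as a source of the venous chemokine call was not tested. Venous lists with an adjusted p above 0.05 without 1 sample were chemokines (0.108 without APC replicate 3) and interferon-gamma (0.465 without APC replicate 2). Others were oxidative phosphorylation (0.24 without APC replicate 2 and 0.0873 without PBS replicate 2) and type I interferon (0.822 without APC replicate 2 and 0.089 without PBS replicate 1). General capillary medians that moved by over 1.5 times were 0.04 (MHC class II) without APC replicate 1, and 0.26 (NF-kB) without APC replicate 3. Further general capillary medians were 0.08 (NF-kB), 0.26 (heat shock) and -0.53 (surfactant) without PBS replicate 2, and 0.22 (NF-kB), 1.31 (immunoglobulin secretion) and -0.21 (surfactant) without PBS replicate 3. Venous medians that moved by over 1.5 times were 0.11 (NF-kB) and -0.68 (type I interferon) without APC replicate 1, and -0.13 (interferon-gamma), -0.06 (oxidative phosphorylation) and -0.09 (type I interferon) without APC replicate 2. Further venous medians were 0.70 (chemokines) without APC replicate 3, and 0.62 (NADPH oxidase), 1.86 (chemokines) and 0.79 (granule protein) without PBS replicate 1. Venous medians were also 0.10 (NF-kB) and 0.78 (granule protein) without PBS replicate 2, and 1.76 (NADPH oxidase), 0.34 (NF-kB) and 2.43 (granule protein) without PBS replicate 3.

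In B cells the lists of naive lymphocyte genes, which mark cells that have not met antigen (median -0.34, adjusted p = 0.00338), and of immediate-early genes (median -0.30, adjusted p = 7.51e-05) were called lower in APC. The adjusted p of all B cell lists of this paragraph was 0.933 to 0.937 with an estimated correlation. Klf2 was at -0.45 (SE 0.14) and S1pr1 at -0.38 (SE 0.12). The interferon-gamma list was lower (median -0.07, and 0.02 without APC replicate 2). Oxidative phosphorylation (31 of 32 members above 0, median 0.16), ribosomal (28 of 28, median 0.13), complement (median 0.44) and NADPH oxidase (median 0.15) lists were higher. B cell lists had an adjusted p above 0.05 without 1 sample for NADPH oxidase (0.108 without APC replicate 1, 0.0568 without PBS replicate 1 and 0.111 without PBS replicate 2) and complement (0.082 without APC replicate 2, 0.109 without APC replicate 3 and 0.0779 without PBS replicate 2). Further such lists were immediate-early (0.143 without PBS replicate 3) and interferon-gamma (0.211 without APC replicate 2, 0.0854 without APC replicate 3 and 0.19 without PBS replicate 3). By edgeR 0 of 11701 genes passed, with 718 at an unadjusted p under 0.05 and 3 called by DESeq2. The genes with the smallest p included the endoplasmic reticulum chaperone genes Pdia3 (0.62, SE 0.10), Hsp90b1 (0.57, SE 0.10) and Pdia6 (0.63, SE 0.13), with adjusted p = 0.724, 0.724 and 0.779, and Ralgds (-0.69, SE 0.14) and Plxnc1 (0.57, SE 0.12). B cell medians that moved by over 1.5 times were 0.75 (complement) and -0.12 (interferon-gamma) without APC replicate 1, and 0.23 (NADPH oxidase) and 0.22 (complement) without APC replicate 2. Further B cell medians were 0.70 (complement), 0.08 (ribosomal), -0.18 (immediate-early) and 0.10 (oxidative phosphorylation) without PBS replicate 1, and 0.20 (complement), -0.12 (interferon-gamma) and -0.16 (naive lymphocyte) without PBS replicate 2. B cell medians were also 0.95 (complement), 0.22 (ribosomal) and -0.15 (immediate-early) without PBS replicate 3.

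In T cells the list of cytotoxic effector genes was called lower in APC (11 of 15 members below 0, median -0.26, adjusted p = 0.00212), with the interferon-gamma gene Ifng at 17.5 CPM in PBS and 6.45 in APC (-1.46, SE 0.38) and Gzma at -1.23 (SE 0.51). The adjusted p of all T cell lists of this paragraph was 0.933 to 0.952 with an estimated correlation. The heat shock list was higher (median 0.36, adjusted p = 0.000101), with Hspe1 at 0.41 (SE 0.13), and its median turned to -0.0044 without APC replicate 1. The lymphocyte activation list was higher (median 0.19, adjusted p = 0.0492), and its median turned to -0.09 without PBS replicate 2 and without APC replicate 2. Oxidative phosphorylation was higher (0.05), and the MHC class II (-0.22), mitochondrially encoded (-0.14) and surfactant (-0.14) lists were lower. T cell lists had an adjusted p above 0.05 without 1 sample for MHC class II (0.352 without APC replicate 2, 0.185 without APC replicate 3, 0.435 without PBS replicate 1 and 0.164 without PBS replicate 3) and heat shock (0.585 without APC replicate 1 and 0.083 without PBS replicate 2). So it was for lymphocyte activation (0.132 without APC replicate 1, 0.783 without APC replicate 2, 0.369 without PBS replicate 1 and 0.799 without PBS replicate 2) and mitochondrially encoded (0.329 without APC replicate 2). The same was so for oxidative phosphorylation (0.331 without APC replicate 1, 0.21 without APC replicate 3, 0.889 without PBS replicate 1 and 0.14 without PBS replicate 2) and surfactant (0.134 without PBS replicate 3). By edgeR 0 of 11813 genes passed, with 379 at an unadjusted p under 0.05 and 1 called by DESeq2. S100a8 (2.40, SE 0.44) and S100a9 (1.94, SE 0.39), which are neutrophil transcripts, Adamts6 (-0.49, SE 0.09), Dtx1 (0.98, SE 0.20) and Hsp90b1 (0.40, SE 0.09) had the smallest p, each with an adjusted p of 0.999. T cell medians that moved by over 1.5 times were -0.60 (MHC class II) and 0.02 (oxidative phosphorylation) without APC replicate 1, and -0.10 (MHC class II), -0.03 (mitochondrially encoded), 0.09 (oxidative phosphorylation) and -0.21 (surfactant) without APC replicate 2. Further T cell medians were 0.39 (lymphocyte activation) and -0.09 (surfactant) without APC replicate 3, and 0.03 (lymphocyte activation), 0.0027 (oxidative phosphorylation) and -0.21 (surfactant) without PBS replicate 1. T cell medians were also -0.40 (MHC class II) without PBS replicate 2, and 0.58 (lymphocyte activation), 0.13 (oxidative phosphorylation) and -0.04 (surfactant) without PBS replicate 3.

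In monocytes the list of immediate-early genes was called lower in APC (median -0.71, camera adjusted p = 1.34e-11), with Jun at -0.98 (SE 0.25) and Egr1 at -0.84 (SE 0.20). Of its 17 members, all with negative fold changes, 11 passed when adjusted over the list alone and 0 over all genes. The adjusted p of all lists of monocytes and natural killer cells was between 0.933 and 0.952 with an estimated correlation. Monocyte lists called higher were those of cell cycle genes (median 0.90, adjusted p = 0.000173), with the proliferation marker Mki67 at 1.53 (SE 0.35), and of granule protein genes (median 1.11), with Lcn2 at 3.87 (SE 1.01) and Cd177 at -1.04 (SE 0.27). Granule genes are neutrophil transcripts, and the neutrophil genes S100a8 and Retnlg had higher medians in APC over 20 cell types outside neutrophils and monocytes. Monocytes themselves were left out of these medians. Glycolysis (0.28), lysosome (0.18), oxidative phosphorylation (0.23), ribosomal (0.17) and mitochondrially encoded (0.23) lists were higher, and MHC class II (-0.44) and naive lymphocyte (-0.39) lists lower. In natural killer cells the MHC class II (0.85), MHC class I (0.18), NADPH oxidase (0.12), oxidative phosphorylation (0.17), ribosomal (0.18) and lymphocyte activation (0.19) lists were higher and the immediate-early (-0.15) and surfactant (-0.34) lists lower. Monocyte lists had an adjusted p above 0.05 without 1 sample for MHC class II (0.0617 without APC replicate 2 and 0.138 without PBS replicate 3) and ribosomal (0.191 without PBS replicate 2). Others were glycolysis (0.142 without APC replicate 2, 0.099 without PBS replicate 1 and 0.0884 without PBS replicate 2) and lysosome (0.0812 without APC replicate 2 and 0.143 without PBS replicate 1). Further such lists were mitochondrially encoded (0.133 without APC replicate 3, 0.0646 without PBS replicate 1 and 0.13 without PBS replicate 2) and naive lymphocyte (0.413 without APC replicate 1, 0.0728 without APC replicate 2, 0.752 without PBS replicate 1 and 0.0518 without PBS replicate 2). So it was for granule protein (0.182 without APC replicate 2 and 0.0665 without PBS replicate 2). Natural killer cell lists had an adjusted p above 0.05 without 1 sample for MHC class I (0.313 without PBS replicate 2) and MHC class II (0.305 without APC replicate 2). The same was so for NADPH oxidase (0.0579 without APC replicate 3, 0.0696 without PBS replicate 1 and 0.0983 without PBS replicate 2) and immediate-early (0.174 without APC replicate 2, 0.137 without APC replicate 3 and 0.969 without PBS replicate 3). Others were lymphocyte activation (0.265 without APC replicate 1, 0.0758 without APC replicate 2, 0.0767 without PBS replicate 1 and 0.681 without PBS replicate 2) and surfactant (0.107 without APC replicate 1 and 0.175 without PBS replicate 2). Monocyte medians that moved by over 1.5 times were -0.82 (MHC class II), 0.25 (ribosomal), -0.17 (naive lymphocyte) and 0.36 (oxidative phosphorylation) without APC replicate 1, and -0.27 (MHC class II), 0.45 (cell cycle), 0.08 (ribosomal), 0.10 (glycolysis), 0.10 (lysosome), 0.54 (granule protein) and 0.14 (oxidative phosphorylation) without APC replicate 2. Further monocyte medians were 0.55 (cell cycle) without APC replicate 3, and -0.01 (naive lymphocyte) and 0.14 (oxidative phosphorylation) without PBS replicate 1. Monocyte medians were also 0.07 (ribosomal) and 0.18 (glycolysis) without PBS replicate 2, and -0.22 (MHC class II) and 0.30 (ribosomal) without PBS replicate 3. Natural killer cell medians that moved by over 1.5 times were 0.09 (ribosomal), -0.29 (immediate-early) and 0.10 (lymphocyte activation) without APC replicate 1, and 0.22 (MHC class II) and 0.18 (NADPH oxidase) without APC replicate 2. Further natural killer cell medians were 1.51 (MHC class II) and 0.33 (lymphocyte activation) without APC replicate 3, and 0.29 (NADPH oxidase), 0.10 (lymphocyte activation) and -0.59 (surfactant) without PBS replicate 1. Natural killer cell medians were also 0.08 (MHC class I), 0.18 (NADPH oxidase), -0.26 (immediate-early) and -0.15 (surfactant) without PBS replicate 2, and 0.23 (NADPH oxidase), 0.28 (ribosomal), -0.02 (immediate-early) and 0.33 (lymphocyte activation) without PBS replicate 3.

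Over all cell types camera called 141 of 651 pairs of list and cell type, 74 higher and 67 lower. The 9 other splits of the 6 samples into 3 and 3 gave 157 to 262 called pairs. The number of calls thus does not set the labelled groups apart. With an estimated correlation 0 were called by camera, the smallest adjusted p was 0.268, and 27 pairs had an unadjusted p under 0.05. At the preset correlation 46 of the 141 calls held without each of the 6 samples in turn, and 95 ended without at least 1 of them. Heat shock was called higher in 9 cell types and lower in interstitial macrophages, and immediate-early genes lower in 10 and higher in fibroblasts and alveolar type 2 cells. Of the heat shock calls those of aerocyte and general capillary endothelial cells held without each sample, while the median of interstitial macrophages (-0.22) turned to 0.07 without PBS replicate 1 and that of arterial cells (0.24) to -0.13 without APC replicate 1. Complement was called higher in 8, granule proteins in 7, NF-kB targets in 6 (and lower in neutrophils), immunoglobulin secretion in 5, and NADPH oxidase and endothelial activation in 3 each. Surfactant was called lower in 8 cell types, and interferon-gamma response and naive lymphocyte genes in 6 each. MHC class II was called higher in 2 and lower in 6, MHC class I in 1 and 4, oxidative phosphorylation in 5 and 9, and ribosomal proteins in 4 and 4. Called in fewer cell types were cell cycle (3 higher, 1 lower), classical macrophage activation (3 higher), pro-inflammatory cytokines (2 higher), chemokines (2 higher, 1 lower), type I interferon (2 and 1), mitochondrially encoded transcripts (2 and 3), lymphocyte activation (2 and 2), cytotoxic effector genes (1 and 1) and lysosome (1 and 1). Glycolysis was called higher in 1, and alternative macrophage activation and phagocytic receptors lower in 1 each. Other medians that changed sign without 1 sample were classical activation (-0.01 without PBS replicate 2) and immunoglobulin secretion (-0.12 without APC replicate 2, -0.09 without PBS replicate 2) in alveolar macrophages. In alveolar type 1 cells these were ribosomal (0.03 without PBS replicate 3), immediate-early (0.04 without APC replicate 3, 0.07 without PBS replicate 3) and naive lymphocyte genes (0.03 without APC replicate 3). Pericytes had MHC class II at 0.09 without PBS replicate 3 and surfactant at 0.02 without APC replicate 2, smooth muscle cells chemokines at 0.02 and surfactant at 0.07 without PBS replicate 3, and unnamed cluster 5 oxidative phosphorylation at 0.01 without PBS replicate 3. Camera called hypoxia, apoptosis, extracellular matrix, inflammasome and mineralisation in 0 cell types.

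Transcripts of neutrophils and of alveolar type 2 cells were also measured in other cell types. S100a8, a calcium-binding protein gene of neutrophils, was measured over 20 cell types other than neutrophils and monocytes. Its median was 14.3, 14.1 and 43.7 CPM in PBS and 43.9, 149 and 129 in APC (exact permutation p = 0.1). S100a9, its partner gene, overlapped between the groups, with 81.5 CPM in PBS replicate 3 and 71.4 in APC replicate 1 (exact permutation p = 0.2). Neutrophils held 40790 ± 2365 CPM of S100a8 in PBS and 83432 ± 23698 in APC (n = 3, exact permutation p = 0.1). Sftpc had a median of 258 ± 58.5 CPM in PBS and 155 ± 21.5 in APC over 21 cell types outside alveolar type 2 cells (n = 3, exact permutation p = 0.1). Igkc, an immunoglobulin light chain gene, had a median of 619 CPM in PBS replicate 3, 211 and 464 in APC replicates 1 and 2, and 31.9 to 63.0 in the other samples (exact permutation p = 1).

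**Figure D3:**
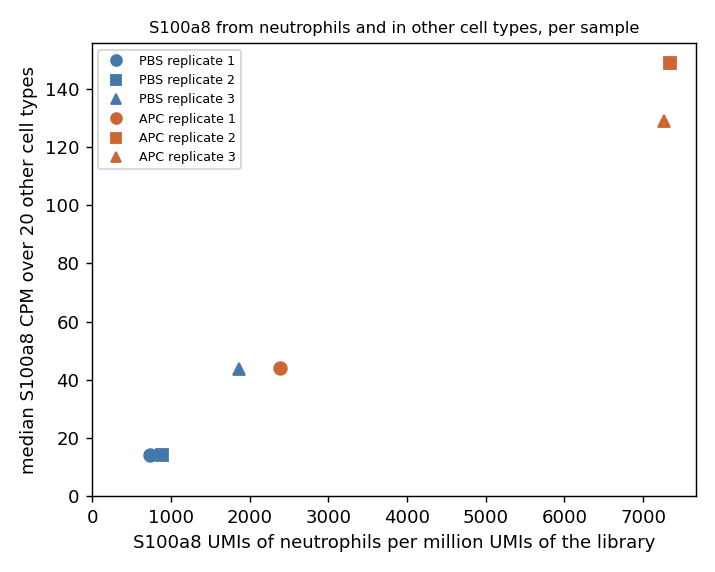
S100a8 CPM that neutrophils contribute to the whole library (x axis) and the median S100a8 CPM over 20 other cell types, monocytes left out (y axis), 1 point per sample. APC replicates 2 and 3 hold 7336 and 7267 on the x axis and 149 and 129 CPM on the y axis, and the other 4 samples lie at or below 2387 and 43.9 CPM.

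Cirbp, a cold-inducible RNA-binding protein gene, was among the genes with the smallest p in several cell types and was lower in APC in 22 of 22 cell types and clusters. The groups did not overlap in 19 of these, and 19 had an unadjusted p under 0.05, but 0 passed the threshold by edgeR (smallest adjusted p = 0.12). The cell types come from the same 6 samples, and in the other 9 splits of these the gene separated in most cell types reached 8 to 22 of them, with Igha at 22. The median log2 fold change was -0.73, from -0.97 in neutrophils to -0.10 in type 2 innate lymphoid cells. Rbm3, another cold-inducible gene, was also below 0 in 22 of 22 (median -0.43). The chaperone genes Hspa8 (median 0.34), Hsp90b1 (0.30), Ahsa1 (0.37) and Ahsa2 (0.60) were above 0 in 22 of 22, while the inducible Hspa1a was below 0 in 16 of 21. These directions held with RLE size factors, and with no low-count filter Rbm3 was below 0 in 21 of 22 and Hspa1a in 17 of 22. Chaperone genes did not all go in the same direction: like Hspa1a, Hspa1b was mostly below 0 (15 of 21, median -0.40). Dnajb1 was below 0 in 14 of 22 (median -0.09). Cirbp, Rbm3, Ahsa1, Ahsa2 and the count over cell types were chosen after the values had been seen.

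**Figure D4:**
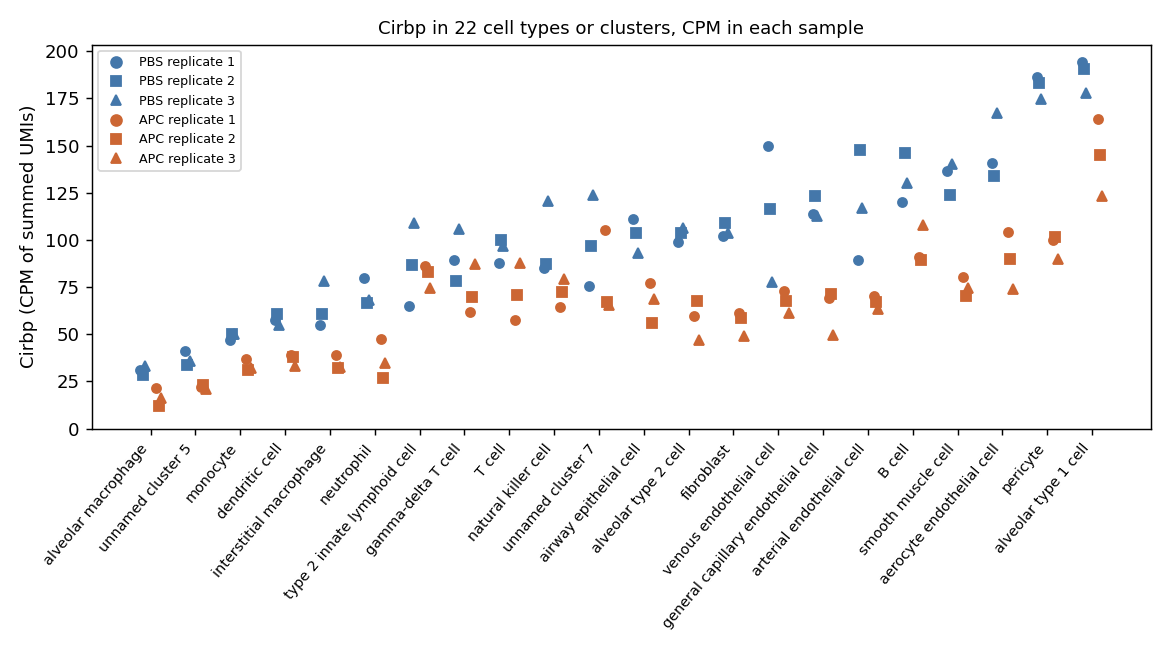
Cirbp level (CPM of summed UMIs, y axis) in 22 cell types or clusters (x axis), ordered by the PBS mean, 1 point per sample. In 19 of the 22 all 3 APC samples lie below all 3 PBS samples, for example fibroblasts at 105 ± 3.58 CPM in PBS and 56.2 ± 6.43 in APC.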

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

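The comparison of gene lists between cell types was chosen after the list results had been seen, and the differences below were not tested. A list is given where it was called higher in one cell type and lower in another and the mean log2 CPM of its members separated all APC from all PBS samples in opposite directions. This held for 12 pairs of cell types and 5 lists. All of these calls were at the preset correlation, and 0 were made with an estimated correlation. Each value is the APC minus PBS difference of the mean log2 CPM in the first cell type minus that in the second.

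Immediate-early genes were higher in fibroblasts (0.397) and lower in airway epithelial cells, interstitial macrophages, monocytes and unnamed cluster 5 (a macrophage-like cluster led by Mmp12 and Spp1), with differences of 0.609, 0.754, 0.961 and 0.677. Oxidative phosphorylation genes were higher in B cells and lower in aerocyte and venous endothelial cells (differences of 0.279 and 0.266), and higher in neutrophils and lower in the same endothelial cells (0.475 and 0.461). The calls of oxidative phosphorylation ended in aerocyte cells without APC replicate 2 (adjusted p = 0.0726) and in venous cells without APC replicate 2 (0.24) or PBS replicate 2 (0.0873). Ribosomal protein genes were higher in neutrophils and lower in gamma-delta T cells (0.751). Mitochondrially encoded transcripts were higher in monocytes and in neutrophils and lower in T cells (0.344 and 0.604). Those of the mitochondrially encoded list ended in T cells without APC replicate 2 (0.329) and in monocytes without APC replicate 3 (0.133), PBS replicate 1 (0.0646) or PBS replicate 2 (0.13). Cytotoxic effector genes were higher in interstitial macrophages and lower in T cells (1.391). Such genes belong to natural killer and T cells, and free RNA or doublets as their source in macrophages were not tested.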

How the results depend on the processing

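Thinning the libraries of a cell type to 1 total and neutrophils without cluster 50 (log2 fold change of the share 1.00, against 0.52) were chosen after seeing the data, and all other alternatives were planned. The count of 14 genes was 13 with RLE size factors, 13 with the stricter cell filter and 15 at resolution 2. It moved to 2417 with no low-count filter, 371 with DESeq2, 26 with doublets kept, 4 at resolution 0.5 and 9 after thinning, and ranged from 2 to 86 when 1 sample was left out. The cause of these moves was not tested. None of the 14 genes changed direction in any alternative that gave a value, which for left-out samples followed largely from groups that did not overlap. Of them 13 passed with RLE, 14 with no filter, 10 with DESeq2, 8 with the replicate block, 13 with the stricter filter, 12 at resolution 2, 5 with doublets kept, 4 at resolution 0.5, and 1 each without PBS replicate 1 and without PBS replicate 2.

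The replicate numbers showed no pairing of the samples. The correlations of deviations, pooled over the genes of all cell types, were 0.000233, -0.143 and -0.236, and 0 of 3 numbers correlated best with their own. A pairing weaker than the other differences between samples would not show in this check, so it is not excluded. With the replicate block 42 genes and 165 list pairs were called, although 6 of the 14 genes no longer passed, and by cell type 2 in B cells, 6 in natural killer cells, 0 in general capillary endothelial cells and 16 in venous endothelial cells.

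By cell type, without the low-count filter and with DESeq2 the counts were 114 and 3 in B cells, 8 and 1 in T cells, 1 and 21 in fibroblasts, 153 and 116 in general capillary cells, 334 and 13 in monocytes, 589 and 49 in neutrophils and 301 and 49 in venous cells, and 129 without the filter in natural killer cells. In general capillary cells the count of 1 became 0 with RLE, the stricter filter and resolution 2. In natural killer cells 9 became 0 with doublets kept, 1 at resolution 0.5 and 3 after thinning. In venous cells 3 became 23 with doublets kept and 1 at resolution 0.5. Leaving out 1 sample gave 0 to 2 in B cells, 0 to 1 in fibroblasts, 0 to 3 in general capillary cells, 0 to 44 in monocytes, 0 to 15 in natural killer cells and 0 to 24 in venous cells.

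The 141 list calls became 0 with an estimated correlation, 213 with no filter and 147 to 245 when 1 sample was left out. Without PBS replicate 3 the NF-kB list in neutrophils reversed to 0.0277 (range -0.843 to 0.0277 over the samples left out), and the activation list in T cells to -0.0924 without PBS replicate 2 and -0.0868 without APC replicate 2 (range -0.0924 to 0.581). Of 38 list calls in the main cell types, 35 to 37 were kept by each alternative that used all samples and the preset correlation, and 25 to 32 when 1 sample was left out. By edgeR 0 cell types passed for their share in each alternative, against 2 at an unadjusted p under 0.05 in the reported test. The B cell log2 fold change ranged from -0.55 to 0.01 (0.0079 without APC replicate 3) and that of general capillary cells from -0.19 to 0.06 (0.0622 without PBS replicate 2). Arterial cells, pericytes and the unnamed clusters gave no value where a resolution did not contain them. Detection was simulated for general capillary cells and monocytes only, and not for classes of few cells such as type 2 innate lymphoid cells (31 in the smallest sample).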

Other observations

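The tests of technical explanations below were chosen after the results had been seen, and their limits were set after their values were known. Counting over other splits of the samples was planned, but what it was to show was also written after the counts had been seen.

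The macrophage and dendritic cell lists named here each had an adjusted p of 0.933 with an estimated correlation. In alveolar macrophages the list of chemokine genes was called higher in APC (13 of 19 members above 0, median log2 fold change 0.34, camera adjusted p = 0.00115), with Cxcl3 at 0.94 (SE 0.26) and Cxcl1 at 0.34 (SE 0.08), as was that of pro-inflammatory cytokine genes (median 0.35, adjusted p = 0.0525 without APC replicate 3), with Il1a at 0.45 (SE 0.13). In interstitial macrophages the list of MHC class II genes was called lower (10 of 10, median -0.64, adjusted p = 8.95e-09), with Cd74 at 15022 CPM in PBS and 9326 in APC, as was that of interferon-gamma response genes (median -0.52), with Irf1 at -0.74 (SE 0.19). In dendritic cells the lists of cell cycle genes (22 of 22, median 0.64, adjusted p = 1.66e-07) and NF-kB targets (median 0.15) were called higher, with the co-stimulatory gene Cd40 at 0.95 (SE 0.22). Lpl, which encodes lipoprotein lipase, was at -1.19 (SE 0.13) in dendritic cells and -1.28 (SE 0.18) in interstitial macrophages, with edgeR adjusted p = 0.117 and 0.345. Alveolar macrophage medians that moved by over 1.5 times were 0.15 (pro-inflammatory cytokines) without APC replicate 1, and 0.18 (chemokines) without APC replicate 3. Further alveolar macrophage medians were 0.14 (pro-inflammatory cytokines) without PBS replicate 2. Interstitial macrophage medians that moved by over 1.5 times were -0.28 (interferon-gamma) without PBS replicate 1. Dendritic cell medians that moved by over 1.5 times were 0.23 (cell cycle) without APC replicate 1, and 0.23 (NF-kB) and 0.29 (cell cycle) without PBS replicate 2. Further dendritic cell medians were 1.74 (cell cycle) without PBS replicate 3.

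The split of the samples that called most genes was not that of the labelled groups. With 6 samples in groups of 3 there are 10 splits, too few for a share under 0.05. Over all cell types the labelled split called 14 genes, and 3 splits, itself included, called as many, with 1191 the highest of the others. That split sets PBS replicates 1 and 2 and APC replicate 3 against the other samples, so the samples have a structure that the labels do not give. It called 787 genes in T cells, a class of 2 clusters whose mix went with it: cluster 8, led by Ctla4, Tnfsf8 and Icos, held 25.6%, 19.5% and 43.5% of T cells in PBS replicates 1 to 3 and 37.5%, 44.4% and 22.1% in APC replicates 1 to 3. Whether these calls hold within each cluster was not tested. For gene lists the labelled split called 141 pairs, the lowest of the 10 splits, and the highest other called 262. For single cell types the labelled and highest other counts, with the number of splits as large including the labelled one, were 1 and 0 in general capillary endothelial cells (1 split), 1 and 1 in monocytes (2 splits), 9 and 22 in natural killer cells (3 splits) and 3 and 12 in venous endothelial cells (3 splits). For shares of cells they were 0 and 4 (10 splits), the 4 being gamma-delta T cells, natural killer cells, plasma cells and proliferating B cells. In PBS replicates 1 to 3 and APC replicates 1 to 3, proliferating B cells were at 0.849%, 0.245%, 3.43%, 4.29%, 3.36% and 0.297%, and plasma cells at 0.312%, 0.096%, 2.94%, 1.15%, 2.53% and 0.191%.

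3 technical explanations were weighed for this structure. For the summed depth of the libraries, the split still called 1150 genes with those of each cell type thinned to 1 total (UMIs per cell were not matched). The fits already scale to the library total, so thinning mainly lowers power and does not decide on depth. Free immunoglobulin RNA is argued against as the whole cause, since the split called 1115 genes without immunoglobulin genes. An exchange of the labels of PBS replicate 3 and APC replicate 3 could give such a split and cannot be told apart from other causes. In at least 11 of the 22 cell types 17 genes separated the labelled groups, against 0 to 10 in the other splits, but S100a8, S100a9, Sftpc and Sftpa1 among them may be free RNA, and a difference in handling that followed the labels would do the same. Differences between animals, such as the course of infection, were not tested.

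The fall of Cirbp across cell types may have a technical or a biological cause. Free RNA as the whole cause is argued against, since in 9 cell types the level fell by more UMIs per cell than neutrophils, the lowest cell type, held in PBS (0.323 ± 0.0298, n = 3), with the largest fall of 1.67 UMIs per cell in airway epithelial cells. With the libraries thinned to 1 total, the median log2 fold change of Cirbp was -0.68 (-0.678, against -0.73 before). Fold changes are already scaled to the library total, so thinning could hardly move this value and does not decide on depth. Temperature or time during handling stays open, because neither is given in the labels and both could follow the groups: the immediate-early list had a median above 0 in 7 of 22 cell types and below 0 in the others. An effect of the treatment itself stays open too and was not tested.

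Neutrophil and alveolar type 2 transcripts in other cell types are consistent with free RNA. Within each sample the median S100a8 to S100a9 ratio of cell types other than neutrophils and monocytes lay within 1.24-fold of that of neutrophils. The median Sftpc to Sftpa1 ratio lay within 1.12-fold of that of alveolar type 2 cells. Doublets with neutrophils are argued against as the main cause of the median difference over 20 cell types. Without cells of 20 or more S100a8 UMIs the median log2 ratio of APC to PBS was 2.11, against 2.23 with them. This median does not decide on single cell types. Without such cells, venous S100a8 fell from 632 to 30.4 CPM in APC replicate 1 and from 164 to 89.5 in APC replicate 3. Differences of S100a8, Retnlg, Sftpc and Sftpa1 outside their source cells may thus reflect the suspension or, in single cell types, doublets. A change within those cells was not separated from these. The same holds for the granule protein, surfactant and immunoglobulin lists outside neutrophils, alveolar type 2 cells and plasma cells, for which no ratio was tested. Monocytes were left out of the S100a8 and Retnlg measures, so neutrophil RNA in monocytes was not measured. Free RNA was not tested either for cytotoxic effector genes in interstitial macrophages and MHC class II genes in natural killer and T cells. Neither free RNA nor doublets were tested for chemokine genes in venous cells.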
